A study of Mus musculus with 3 samples.

How the data were processed

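Genomic DNA from the lungs of 3 mice was amplified at the Cftr locus by PCR and sequenced, 1 library per mouse. The mice carried the CFTR G542X nonsense allele, in a strain that the labels name B6-Tg(CFTRG542X)Cwr. Tg is the usual symbol for a transgene. They had received lipid nanoparticles made with the ionizable lipid CHCha-10 through the trachea, and lungs were collected 3 days after dosing. The particles carried a cargo named ABE/A9. An adenine base editor (ABE) is a Cas9 nickase joined to an adenosine deaminase, which turns A into inosine, and inosine is read as G. The labels do not say what A9 stands for. All 3 samples form a single treated group with separate library names for mouse 1, mouse 2 and mouse 3, and no untreated sample was analysed here. Per the labels' protocols, DNA was amplified with Q5 polymerase and barcodes were added in a second PCR. No molecular identifiers are mentioned, so reads are not independent molecules, and every interval, floor and p-value computed on reads covers counting error only.

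The deposited values are raw read counts per allele, where an allele is a distinct aligned sequence in a 40-base window, per the file headers. The deposited percent of each allele is its reads divided by all reads of that table, and the percents were recomputed from the counts without a difference. Other deposited columns give the number of deleted, inserted and substituted bases of each allele. The tool that aligned the reads, its version, its read filters and the genome build are not given in the sources used here. A filter on read quality or on reads that fail to align would change both the background and the share of long deletions. No genome was given, so the window was not placed on a chromosome, and whether it is mouse or human sequence was not determined. Which copies of the gene the amplicon covers, and so of which copies each share of reads is a share, was therefore not determined either.

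The window reads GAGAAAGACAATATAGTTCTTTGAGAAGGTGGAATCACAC. Positions are counted from 1 at its 5′ end. The 20-base guide sequence named with the tables, ATATAGTTCTTTGAGAAGGT, takes positions 11 to 30. It holds a TGA at positions 22 to 24, which was taken as the G542X stop codon, and in that frame the window covers 13 whole codons, 535 to 547. Substitutions are written with the window's base first, then the position, then the read's base. Every listed allele was compared base by base with the window. The 1 read with an insertion was left out of the counts per position but kept in totals, and a base called N (5 reads, 3 in mouse 1 and 2 in mouse 2) or deleted was counted as not changed.

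Before the data were examined, the main measure was fixed as A-to-G at the A of the TGA (A24G), with the other 5 adenines of the guide sequence as bystanders. The rule for named positions, also fixed then, was every adenine of the guide sequence and any substitution above 0.2% of reads in all 3 mice. The rule for named alleles was the 10 most frequent by mean percent. The tables showed that T22C was the only substitution past that rule, which is A-to-G on the strand opposite to the listed one. All results for T22C were therefore chosen after seeing the data and were computed in the same way as those planned for A24G. Both are reported.

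Shares are given as mean ± SD over mice (n = 3) with exact Clopper-Pearson 95% intervals per mouse. Pairs of bases were compared within each mouse by an exact McNemar test on reads changed at only 1 of them, and over mice by an exact two-sided sign-flip permutation test, whose smallest p with 3 mice is 0.25. Changes on the same read were tested by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the tests of A24G and T22C together, and mice were compared with each other by chi-square tests on reads, which compare these libraries. A count of 0 was read as up to 3 reads. Over all alleles, with those under 10 reads in a pair of mice summed, chi-square tests gave p = 0.184 for mice 1 and 2, 0.550 for mice 1 and 3 and 0.527 for mice 2 and 3. For T22C alone, mouse 2 differed from both others (adjusted chi-square p = 3.5e-05 each), while mice 1 and 3 did not differ (p = 0.965). These tests do not rule out that libraries 1 and 3 share a source. They were counted as separate mice because the labels name them so, and their mean as 1 replicate was an alternative added after seeing the data. Counting was tested on simulated data: in 3 simulated libraries, 12 of 12 simulated read numbers were recovered exactly. The simulated reads were already aligned, held the same deletion away from the TGA, and had no insertion or N. The alignment and the handling of such reads were therefore not tested.

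Total depth was 40496 reads in mouse 1, 42415 in mouse 2 and 43193 in mouse 3, so that a count of 0 allows a share of up to 0.00741%, 0.00707% and 0.00695%. Alternatives changed the reads used as the denominator, the minimum size of an allele, the weighting of mice and the mice included. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.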

Results

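The tables describe amplicon sequencing of a 40-base window around the G542X stop codon in lung DNA of 3 treated mice, read to assess base editing. Depth was similar between libraries, from 40496 reads in mouse 1 to 43193 in mouse 3. The tables listed 210, 219 and 213 alleles in mice 1, 2 and 3. The window sequence without any change made up 92.2% ± 0.42 of reads (SD, n = 3). The most frequent changed allele, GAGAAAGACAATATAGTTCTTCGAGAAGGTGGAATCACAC, made up 6.16% ± 0.39. These 2 alleles together held 98.4% ± 0.04 of reads. The other 8 of the 10 most frequent alleles each differed from the window at 1 base and had mean shares between 0.0325% and 0.0689%. A total of 98 of the 385 distinct alleles were seen in all 3 mice. No untreated lung was analysed here, so background was read from other substitutions in the same libraries.

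The question put to these libraries was how often the stop codon was changed. A single substitution stood apart, T22C, at the first base of the TGA. It was read in 2446 of 40496 reads in mouse 1, which is 6.04% (95% interval 5.81 to 6.28). It was read in 2867 of 42415 reads in mouse 2, or 6.76% (6.52 to 7.002), and in 2612 of 43193 reads in mouse 3, or 6.05% (5.82 to 6.28). The mean was 6.28% ± 0.41 (SD, n = 3). T-to-C on the listed strand is A-to-G on the opposite strand, the change that an adenine base editor makes. On the reverse complement of the guide sequence, ACCTTCTCAAAGAACTATAT, the changed base is A9, counted from its 5′ end, and the next 3 bases are TGT. T22C was the only 1 of the 120 possible substitutions in the window to exceed 0.2% of reads in all 3 mice. The substitution with the next highest mean was T30G at 0.0958% ± 0.006, and the median over the other 119 substitutions was 0.00956%, the lowest being G28C at 7.7e-04%.

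**Figure D1:**
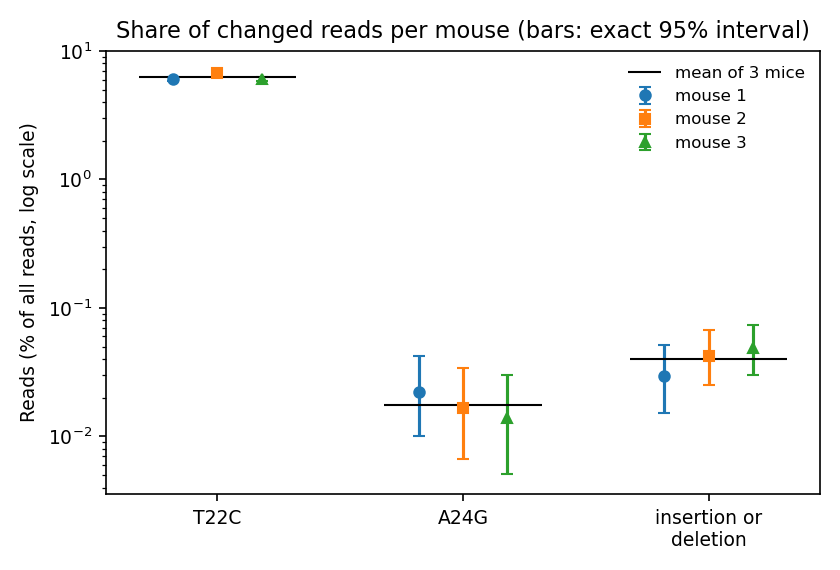
Percent of all reads (log axis) with T22C, with A24G or with an insertion or deletion in mice 1, 2 and 3; symbols are single mice, vertical bars exact 95% intervals of the reads, and horizontal lines the mean of the 3 mice. T22C lay between 6.04% and 6.76%, while A24G stayed at or below 0.0222% and insertions or deletions at or below 0.0486%.

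T22C was far above the other changes at the same base. T22G, which gives the glycine codon GGA, had a share of 0.0175% ± 0.003, and T22A one of 0.0032% ± 0.0028 (SD, n = 3). T22G was seen in 8, 6 and 8 reads in mice 1, 2 and 3, and T-to-G at the 9 T bases of the window averaged 0.0225% ± 0.0007 per base. T30G carried that mean, and the 7 T bases other than T30 and T22 averaged 0.0128% ± 0.0006, below T22G. Their shares ran from 0.0016% to 0.0246%, with 3 of the 7 above T22G. T22C reads were 245, 221 and 261 times as many as reads with T-to-C at the T of the window with the next highest count in mice 1, 2 and 3.

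At the level of the codon, T22C turned TGA (stop) into CGA (arginine). Over reads with all 3 bases of the codon called, arginine codons made up 6.28% ± 0.41 and stop codons 93.6% ± 0.41. Sense codons other than arginine made up 0.104% ± 0.007. The most frequent of these was the leucine codon TTA at 0.0474% ± 0.0098, made by G23T. Tryptophan (TGG) was read in 19 reads over all mice (0.0152% ± 0.0054) and glycine (GGA) in 22 (0.0175% ± 0.0029). Glycine is the amino acid that the name G542X gives for this codon without the mutation.

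The planned measure, A24G, replaces the A of the TGA on the listed strand and gives tryptophan. It was read in 9, 7 and 6 reads in mice 1, 2 and 3. Its share was 0.0175% ± 0.0043 (SD, n = 3), and the highest upper bound of the exact 95% intervals was 0.0422%, in mouse 1. A24T was read at 0.0110% ± 0.0065 and A24C at 0.0064% ± 0.0038. The other 5 adenines of the guide sequence averaged 0.0112% ± 0.0008 A-to-G. These were A11G at 0.0118% ± 0.0061, A13G at 0.0096% ± 0.0026, A15G at 0.0135% ± 0.0017, A26G at 0.0095% ± 0.0046 and A27G at 0.0118% ± 0.0038. A24G exceeded A15G, the highest of them, by 0.0040 ± 0.0029 percentage points. That difference did not stand out in any mouse, with exact McNemar p of 0.607, 1 and 1. Over mice, the exact two-sided sign-flip p was 0.25, the smallest that 3 mice allow. The difference fell to 0.0023 points without mouse 1 and to 9.0e-04 among reads whose changes are all A-to-G, and it reversed when alleles of 1 read were left out. A24G did not differ between mice beyond counting error (chi-square test on reads, p = 0.649). A-to-G change of A24 was thus not told apart from that of A15 at this depth. A24G lay above the mean of the other 5 adenines in each mouse (0.0222%, 0.0165% and 0.0139% against 0.0104%, 0.0118% and 0.0116%), which was not tested. Outside the guide sequence, A6G (0.0197%), A8G (0.0197%), A10G (0.0183%) and A37G (0.0437%) had higher mean shares than A24G, and the remaining adenines had lower ones.

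Bystander changes were compared next, because the other T bases of the guide sequence are also adenines on the opposite strand. The 7 other T bases of the guide sequence had a mean T-to-C share of 0.0156% ± 0.0008 (SD, n = 3), the highest being T17C (valine to alanine at codon 540) at 0.0229% ± 0.0031. T21C, directly beside T22 and silent in leucine codon 541, had 0.0167% ± 0.0023. T20C, which would give proline at codon 541, had 0.0222% ± 0.0075. T22C exceeded T17C by 6.26 ± 0.41 percentage points, in 3 of 3 mice. In mouse 1, 2445 reads carried T22C without T17C and 7 carried T17C without T22C. The corresponding reads were 2867 and 11 in mouse 2 and 2610 and 8 in mouse 3. The base-10 logarithm of the exact McNemar p was -717.8, -835.6 and -765.1. T22C was chosen for its high share in these same reads, so the direction of this test was set beforehand. Its p covers read counting only. Over mice, the exact sign-flip p was again 0.25. T-to-C at the 8 T bases of the window other than T22 (mean 0.0157%) did not differ from A-to-G at its 16 A bases (mean 0.0163%; permutation test across bases, two-sided p = 0.978; bases are not independent replicates).

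**Figure D2:**
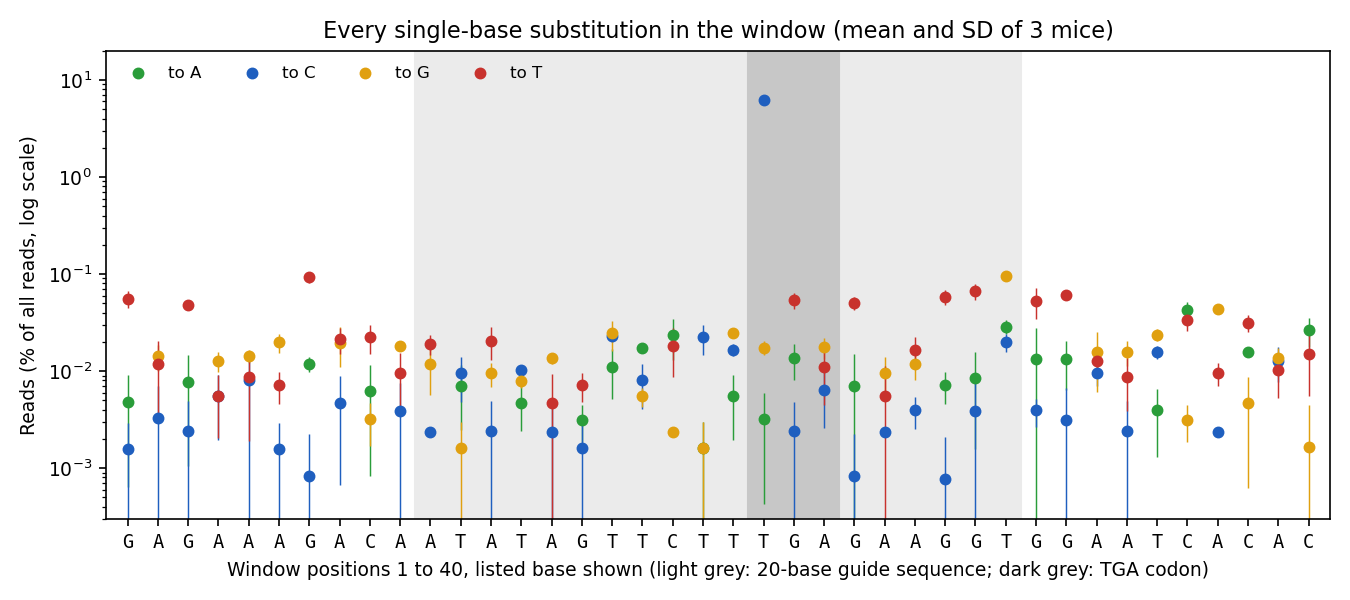
Percent of all reads (log axis) with each single-base substitution at positions 1 to 40 of the window, as mean and SD of 3 mice; colour gives the base read, light grey the 20-base guide sequence, dark grey the TGA codon, and bars whose lower end falls below the axis run to its bottom. T22C, at 6.28%, is the only substitution above 0.2%, and the next, T30G, lies at 0.0958%.

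Changes on the same read were then counted together. Of the T22C reads, 98.1% ± 0.19 (SD, n = 3) had no other change in the window. Another T-to-C was read on 3 of 2446, 5 of 2867 and 4 of 2612 T22C reads. This is a mean share of 0.150% ± 0.026, against 0.121% ± 0.003 of the reads without T22C (two-sided Fisher's exact p of 1, 0.406 and 0.556 in mice 1, 2 and 3). None of the 21 tests of T22C with another T of the guide sequence in a single mouse passed (smallest p = 0.0250, adjusted p = 0.900; Fisher's exact test, Benjamini-Hochberg over these and the A24G tests). Nor did any of the 15 tests of A24G with another adenine, where the smallest p was 1. Only 1 of the 22 A24G reads carried another A-to-G change, so that this share could not be resolved at this depth. Any further substitution was on 7 of the 22 (31.8%, exact 95% interval 13.9 to 54.9), against 7.75% of reads without A24G. With T22C not counted it was on 6 of 22 (27.3%, 10.7 to 50.2), against 1.58% (Fisher's exact test over the reads of all mice, adjusted p = 7.6e-06). This test was added after the values were seen. Single mice had 2 of 9, 1 of 7 and 3 of 6 such reads (adjusted Fisher's exact p of 0.0127, 0.123 and 3.2e-04). Most reads without A24G carried no change at all, so the comparison is not with other background changes. T30G was the only change on 27 of 36, 29 of 43 and 31 of 42 of its reads in mice 1 to 3. For A37G these were 16 of 20, 15 of 18 and 14 of 17, and for A24G 6 of 9, 6 of 7 and 3 of 6. Whether A24G reads differed in this from reads with other background changes was not tested. Any further substitution was read on 1.87% ± 0.13 of T22C reads and 1.58% ± 0.04 of the others, higher on T22C reads in 3 of 3 mice but past the 0.05 threshold in none (Fisher's exact p of 0.311, 0.0926 and 0.422). On 98.5% ± 0.06 of T22C reads, arginine in place of the stop was the only amino acid change in the 13 codons. Reads with an insertion, a deletion or an N were counted as failing this.

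Insertions and deletions were rare. They were found on 12 reads in mouse 1 (0.0296%, 95% interval 0.0153 to 0.0518), 18 in mouse 2 (0.0424%, 0.0252 to 0.0671) and 21 in mouse 3 (0.0486%, 0.0301 to 0.0743). The mean was 0.0402% ± 0.0097 (SD, n = 3). The mice did not differ beyond counting error (chi-square test on reads, p = 0.382). Of the 51 reads, 50 had a deletion and 1 an insertion of 7 bases. The deletions fell into 26 of 1 or 2 bases and 24 of 7 to 43 bases, and 18 of the 50 removed position 22. No allele with an insertion or deletion reached 0.2% in any mouse. T22C reads outnumbered reads with an insertion or deletion 162-fold ± 39.8.

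The T22C shares of the 3 libraries differed by more than read-counting error (chi-square test on reads, p = 4.8e-06). With 1 library per mouse and no molecular identifiers, this test and the intervals beside it compare libraries, and differences between mice were not told apart from those of PCR. The library of mouse 2 was 0.72 percentage points above that of mouse 1 (95% interval 0.39 to 1.05, adjusted chi-square p = 3.5e-05), and the library of mouse 3 minus that of mouse 2 was -0.71 points (-1.04 to -0.38, adjusted chi-square p = 3.5e-05). The libraries of mice 1 and 3 differed by 0.007 points (-0.316 to 0.330; chi-square test, p = 0.965). Without mouse 2, the spread was within counting error. The share of reads with a substitution elsewhere in the window was 1.54%, 1.62% and 1.59% in mice 1, 2 and 3, which did not differ beyond counting error (chi-square test, p = 0.616).

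Background substitutions away from position 22 numbered 2291 over the 3 libraries and were led by G-to-T. The median share of all substitutions other than A-to-G was 0.0087% ± 0.0011 (SD, n = 3). G-to-T averaged 0.0545% ± 0.0050 per G base, against 0.0229% ± 0.0031 for its complement C-to-A per C base, and made up 29.9% of these changes. The G bases were not alike, since G16T lay at 0.0072% ± 0.0024, below that median, and the others ran from 0.0475% to 0.0929%. Of the 10 most frequent background substitutions, 9 were G-to-T, led by G7T at 0.0929% ± 0.0112, and T30G was the exception. Outside the guide sequence the highest A-to-G share was A37G at 0.0437% ± 0.0051, a position singled out after its values were seen.

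**Figure D3:**
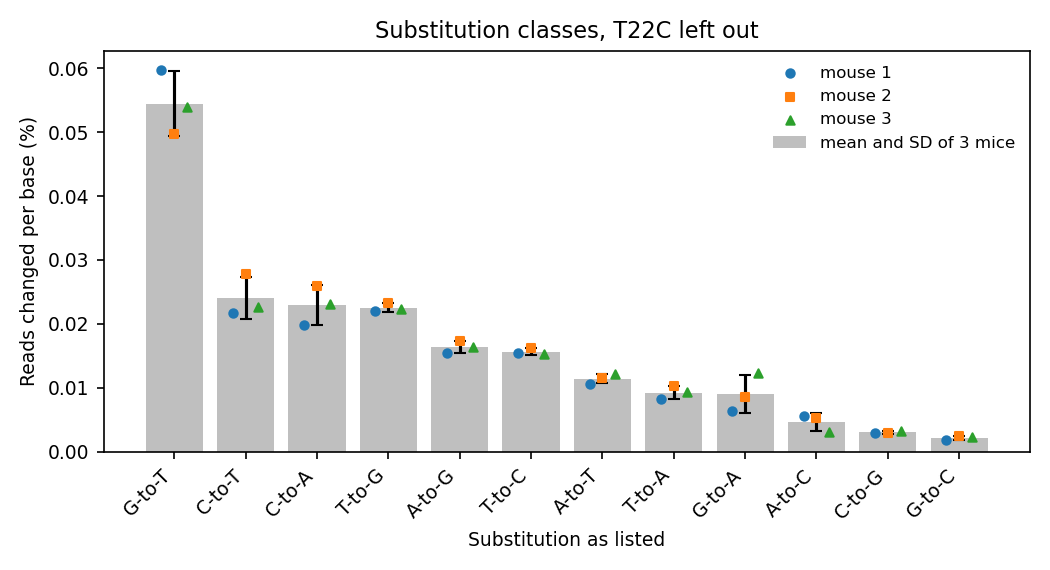
Mean percent of reads changed per base for each class of substitution on the listed strand, with T22C left out; bars are the mean of 3 mice starting at 0, error bars the SD, and symbols single mice. G-to-T, at 0.0545%, was the most frequent class, while T-to-C and A-to-G lay at 0.0157% and 0.0163%.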

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

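All T22C settings were chosen after seeing the data, and those for A24G were planned. The T22C share stayed between 6.04% and 6.40% under all settings tried, including background subtraction (6.27%) and mice 1 and 3 taken as 1 replicate (6.40%). Leaving out each mouse in turn, the p of the spread of T22C between libraries ranged from 2.1e-05 to 0.965, and the last value is without mouse 2; the cause was not tested. The results near background depend on which alleles are kept. With alleles at or above 0.2%, or with at least 10 reads per allele, few or no alleles near background are left, and both settings gave 0 for A24G, for A24G alone, for A24G minus A15G, for indels and for T22C reads with another T-to-C. The 0.2% minimum also gave 0 for the other adenines and the other T bases of the guide sequence, and neither left an A24G read on which to count another A-to-G. With at least 2 reads per allele, A24G fell to 0.0120%, A24G minus A15G reversed to -7.6e-04 percentage points, the median background fell to 0.0063% (with or without T-to-C), indels fell to 0.0103% and T22C reads with another T-to-C to 0.0493%. A24G was 0.0130% among reads with A-to-G changes only and 0.0088% after subtracting the mean of A24C and A24T. Another T-to-C within the guide sequence was on 0.112% of T22C reads. Of the alternatives, 42 planned and 46 added ones left the result unchanged. For shares, this means a value within 1 SD of the reported one. For differences and p-values, it means the same sign or the same side of the 0.05 threshold. Another 14 planned and 6 added ones moved the value, 1 planned one reversed it and 1 added one weakened it. Leaving out 1 of 3 mice cannot move a mean share by 1 SD, so for shares those settings were bound to count as unchanged. An indel share cannot be had among reads without indels. The depth sets a limit of about 0.007% for a change that was not read, and PCR duplicates cannot be recognised.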

Other observations

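The tests in this part were chosen after the result was seen, except the test of other substitutions on reads with several G-to-T changes.

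Long deletions and T22C tended to share reads. Of the 24 reads with a deletion of 7 or more bases, 7 kept position 22, and 6 of these 7 carried T22C (85.7%, exact 95% interval 42.1 to 99.6), against 6.28% of reads without an insertion or deletion. They were 2 of 2 such reads in mouse 1 and 4 of 5 in mouse 2, and mouse 3 had none that kept the base. Deletions of 1 or 2 bases kept the base on 25 reads, and 0 of these carried T22C, which allows a share of up to 13.7%. The share falls as shorter deletions are included, to 6 of 11 reads (54.5%) for deletions of 2 or more bases and 6 of 32 (18.8%, exact 95% interval 7.2 to 36.4; Fisher's exact p = 0.0135, adjusted p = 0.0158) for any deletion.

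If deletions arose irrespective of T22C, the long ones would carry T22C at the share of all reads, and Fisher's exact test argued against this (two-sided p = 4.1e-07, adjusted p = 2.9e-06 over 7 tests of deletion classes; p = 0.0037 without mouse 2, where 2 of 2 reads remained). The alignment could have put a base beside the gap at position 22. Among the 5 long deletions whose nearest deleted base lay over 2 bases away, 4 still carried T22C (Fisher's exact p = 7.4e-05). These 4 ran past the window or to its last base, and the other, at positions 3 to 11, read T. Deletions past the window that kept the base carried T22C on 3 of 3 reads, 2 in mouse 1 and 1 in mouse 2. Those of 5 or more bases within it did so on 3 of 4 reads, all in mouse 2. How the alignment treats gaps at the window's edge was not tested. For deletions of 1 or 2 bases the upper bound of 13.7% lies above 6.28%, so that they are consistent with errors independent of T22C. That the editor may nick and deaminate the same copy stays open, since the series as analysed here has 0 untreated libraries. The division at 5 bases was made after seeing the reads, and the pattern rests on 7 reads, each with a different deletion.

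In the mouse with the lowest ratio, T22C was 220.5 times as frequent as T-to-C at the next T of the window. That size argues against PCR or sequencing error at the level of other T bases. It is not an independent test, because T22C was chosen for its high share, and an error particular to position 22 was not tested. Of the reads changed at position 22, at lowest 99.6% in a mouse read C, but T22C was singled out for its high share, so this value does not bear on adenine deamination as its cause. A variant present before dosing, or reads carried over from another library, could give the same reading. Neither can be told apart from editing here, with 0 untreated libraries.

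G-to-T changes came together on reads. A total of 74 reads without an insertion or deletion carried 2 or more G-to-T changes, up to 5 on 1 read, against 1.65 expected if the 10 G bases changed independently, an excess of 44.8-fold that argues against independent errors. The excess was not particular to G-to-T, since 9 of the 12 classes of substitution had more such reads than expected (one-sided Poisson test, adjusted p under the 0.05 threshold). T-to-G was next by count with 20 against 0.187, and A-to-C had 7 against 0.0318. By observed over expected reads, both of these lay above G-to-T. All 9 classes with any such read passed, some on few reads, such as 2 for G-to-A, 3 for A-to-G and 4 for C-to-A. PCR duplicates cannot be recognised among them, so these small counts say little. Reads with 2 or more G-to-T changes also carried other substitutions, T22C not counted, more often than reads without G-to-T. The share was 12.2% (9 reads, exact 95% interval 5.7 to 21.8) against 1.15%, or 10.6-fold (Fisher's exact p = 2.0e-07). This leaves reads of low quality as a candidate explanation for these 9. Most of the 74 reads carried no other substitution, T22C not counted, and for them low quality was not shown. DNA damage before or during PCR and biological explanations were not tested.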
